A study of Mus musculus with 4 samples.

How the data were processed

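Total RNA from mouse spinal cord was measured on 4 Agilent mouse arrays with 1 dye, Cy3, 1 array for each of 4 groups: control mice with a Matrigel implant and NCTC tumour-bearing mice, each at ZT10 and at ZT22. Whether an array holds 1 mouse or a pool is not given in the sources used here. Per the labels' protocols the RNA was isolated with a ReliaPrep column kit, described there as extraction from cells. It was copied and labelled with a Low Input Quick Amp kit. Per the file headers the arrays are of design 074809, probe positions are on mm9, and the spots were read with Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09. They also give the values as intensity after background subtraction and detrending, with no scaling between arrays. The submitters' processing notes name Agilent Feature Extraction 9.5.1.1 in its place. A value table deposited by the authors holds intensity on the linear scale, 1 value per probe, with 1 common distribution in all 4 columns (median 24.0), and the tool behind it is not given in the sources used here. All 4 arrays lie on 1 slide and were read in 1 scan, and the groups take different positions on it.

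Each array has 62976 spots, 59305 of them not controls, for 56605 probes. Spots marked as outliers by the scanner software were left out, as were control spots, and repeated spots of a probe were averaged on the log2 scale. The outliers numbered 134 for control mice at ZT10, 118 for control mice at ZT22, 108 for tumour-bearing mice at ZT10 and 97 for tumour-bearing mice at ZT22. The processed signal was taken to log2 and the array's 75th percentile subtracted; that percentile was 348, 270.4, 288 and 325 in the same order. A probe counted as measured where the software called it well above background and not saturated, which held for 31173, 30757, 31305 and 31648 probes. Repeated spots of 298 measured probes printed 10 times had a median SD of 0.15, 0.13, 0.14 and 0.12 on the log2 scale. Some single spots strayed further. Between the arrays of a pair, their difference lay at least 2-fold from the probe's own mean difference in 0.80% for tumour at ZT10 and 0.57% at ZT22. For time it did so in 1.45% in control and 0.39% in tumour-bearing mice. Probes were named from RefSeq for GRCm38, used for names alone: 32994 by accession and 10224 by symbol, and 13387 had no RefSeq gene name and were left out of the main comparisons. Of the 24722 genes on the array 11130 had more than 1 probe, and a gene took the value of its brightest probe.

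For each pair of arrays the log2 difference was taken over genes measured on both arrays, and genes at least 2-fold higher or lower were counted; no test is possible on 1 array against 1. A gene measured on 1 array of a pair was given as a bound. It was taken against the lowest signal called well above background on the other array, or against the gene's own signal there where that was higher. Tumour over both times and time over both kinds of mice were fitted together in limma 3.58.1 (R 4.3.3) as additive terms with empirical Bayes moderation over 15284 genes, with 1 residual degree of freedom, 6.29 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The difference of tumour effects was taken as the effect at ZT22 less that at ZT10. Other work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. For each gene the measured values of its other probes were kept beside the brightest, and the 8 nearest measured spots on the slide were looked at for differences of at least 2-fold the same way.

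41 gene lists were written from general knowledge of the genes: clock genes of the dark-phase and of the light-phase limb, ROR receptors, temperature-responsive and heat shock genes, glucocorticoid-responsive genes, immediate early genes, homeostatic and activated microglia, and homeostatic and reactive astrocytes. Others held cytokines and chemokines, interferon-stimulated, acute-phase and complement genes, neuropeptides and their receptors, glutamate, GABA and glycine signalling, pain-related ion channels, and noradrenergic and serotonergic receptors. Cell types were covered by lists for pan-neuronal, motor neuron, myelin, oligodendrocyte precursor, sensory ganglion, Schwann cell, skeletal muscle, erythroid, endothelial, pericyte, meningeal, ependymal, choroid plexus, neutrophil and marrow, lymphocyte, bone and cartilage and adipocyte genes. The last lists held genes of fasting and lipid metabolism, cholesterol synthesis, stress and unfolded protein response, oxidative phosphorylation, cell cycle and reference genes. A list's median was set against 10000 random lists of the same size drawn from the same 20 bins of mean expression, with percentiles outside 2.5 to 97.5 singled out. Lists with fewer than 3 measured members got no percentile. Some genes stand in more than 1 list, Lcn2 among them.

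The groups, comparisons, gene lists, thresholds and the rule for naming genes were chosen before the data were examined. By that rule each pair of arrays names the 10 largest increases and 10 largest decreases among measured genes with a settled symbol. The additive fit names up to 10 genes of lowest adjusted p in each direction past 0.05 or, where fewer than 5 pass, the 5 of lowest p. The difference of tumour effects names the 5 largest each way. The rule also names the 3 largest bounds each way per pair, up to 4 members of each list with the largest difference, and every measured member of both clock lists, the ROR receptors, Cirbp and Rbm3. Some genes that the rule names are not reported here.

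Other processing tried was quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' value table, the mean of a gene's probes, and no detection filter. Stricter and looser detection filters were tried too, as were thresholds of 1.5-fold and 3-fold, an intensity trend and a robust fit in limma, the upper part of the expression range, no clock genes, and random lists not matched on expression. 4 further alternatives were chosen after seeing the data, namely all named transcripts, no spots in disturbed neighbourhoods, agreement of a gene's other probes, and the other probes of list members alone. Median scaling shifts all genes of a pair alike. It can change the sign of a list median, but its percentile only through the random draws. The authors' table nearly repeats quantile normalization. Both settings therefore add little where a call is said to hold.

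The code was tested on simulated data. In 20 simulations per effect with 200 changed genes among 15284, the additive fit recovered 1.7% of genes with a tumour difference of 1.5-fold, 17.4% at 2-fold, 97% at 4-fold and 99.9% at 8-fold. It made 12.5 false calls per simulation, 9.31% of its calls, and for time 8.81% of the calls were false. The simulated noise was independent between genes and alike on all arrays, with no disturbed spots or neighbourhoods. With no effect simulated, 25% of the simulations for tumour and 15% of those for time gave at least 1 call. In a pair of single arrays 276.2 unchanged genes per simulation came out at least 2-fold apart for tumour. Random lists of 15 genes shifted by 0.3 lay at or above percentile 97.5 in 88% of draws, lists of 5 genes in 30%, and unshifted lists of 15 in 2%. Left out as well were 7995 genes above background on no array and the raw spot and background signals, which the processed signal already holds.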

Results

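Gene expression was measured in total RNA from the spinal cord of C3H/HeJ mice with 4 one-colour microarrays, 1 for each of 4 groups. Control mice carried an implant of Matrigel, a gel of basement-membrane proteins. The other mice carried a tumour that the labels call NCTC. Cords were taken at ZT10, late in the light phase, or at ZT22, late in the dark phase; zeitgeber time (ZT) counts the hours after lights-on. The study's title joins tactile pain in mice with cancer to the REV-ERBs, receptors that repress transcription in the circadian clock. The arrays set tumour-bearing against control cords at each time and late dark against late light phase in each kind of mouse. There are no replicates, and a difference between a pair of arrays therefore has neither an error nor a p. Between 30757 and 31648 of the 56605 probes lay well above background on an array (54.3% to 55.9%) and 0 were saturated. The number of arrays limits the precision. Differences below are on the log2 scale, positive where the tumour-bearing mice or ZT22 were higher. In all, 15284 genes were measured on all 4 arrays.

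At ZT10 the comparison asks how the cord of tumour-bearing mice differed late in the light phase. Interferon-stimulated genes, the set that cells switch on in antiviral defence, were lower in the tumour-bearing cord: 9 of 22 measured members were at least 1.5-fold lower and 0 were at least 1.5-fold higher, with a median of -0.49. Ifi44 was lower by 4.28-fold (log2 -2.10) and Usp18, the protease that removes the ubiquitin-like protein ISG15 from other proteins, by 4.00-fold (-2.00). Ifit1 gave -1.55 and Oas1a -1.31. The control array at ZT10 stood apart for this list, 0.35 above the mean of the others, against -0.16 to -0.11 for each of those. The haemoglobin genes were lower too, with all 4 measured erythroid markers at least 1.5-fold lower and a median of -1.34. Hbb-b1 gave -1.77, Hba-a1 -1.36, Hba-a2 -1.31 and Hbb-b2 -1.16. Medians of the astrocyte lists were higher. The secreted iron-binding protein Lcn2 (1.43) and the protease inhibitor Timp1 (1.42) led the reactive set.

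Of the 21 measured reactive astrocyte genes at ZT10, 5 were at least 1.5-fold higher and 0 lower, with a median of 0.21 at percentile 98.2 among 10000 random lists matched on expression. In it H2-D1 gave 1.40 and the oncostatin M receptor Osmr 0.89. Homeostatic astrocyte markers had a median of 0.29 (percentile 99.9), 11 of 14 members positive and 0 at least 1.5-fold higher. Slc1a2, the main glutamate transporter of astrocytes, stood at 0.53, Aldh1l1 at 0.47 against the sign of its other probe, Slc7a10 at 0.47 and Agt at 0.41. Glucocorticoid-responsive genes had a median of 0.22 (percentile 99.6) with 3 of 19 at least 1.5-fold higher. These were the kinase Sgk1 (1.96), Lcn2 (1.43) and Klf9 (0.64, -0.62 with the mean of its probes). Fkbp5 gave -0.51. Ependymal markers had a median of 0.42 (percentile 99.6), 7 of 8 positive, led by Dynlrb2 (0.60), Cdhr4 (0.51), Tmem212 (0.45) and Rarres2 (0.43). Dynlrb2 was lowest on the control array at ZT10, at 0.01 against 0.61 to 0.94 elsewhere, while Cdhr4 was lowest on the tumour-bearing array at ZT22. The ependymal time difference in control mice and difference of tumour effects below share that control array. Genes of fasting and lipid metabolism had a median of 0.22 (percentile 99.3) with 0 of 16 at least 1.5-fold apart. Ppara stood at 0.41, Txnip at 0.40 and Pdk4 at 0.40. The interferon and erythroid medians lay at percentile 0, below all of their random lists. Of 6 other settings laid down in advance, the reactive astrocyte call held in 4, with a median as low as 0.0847, and the homeostatic astrocyte call in 5.

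Most clock genes differed little between the cords at ZT10. The light-phase group had a median of -0.06: Nr1d1, which encodes REV-ERB alpha, gave -0.06, Nr1d2, which encodes REV-ERB beta, -1.19 against the sign of its other probe, and Dbp 0.47. The rest gave Tef -0.17, Hlf -0.25, Per1 0.27, Per2 0.33, Per3 -0.12, Cry2 -0.31, Ciart -0.33, Bhlhe41 0.15, Bhlhe40 0.08 and Usp2 0.00. In the dark-phase group Arntl, which encodes BMAL1, gave 0.07, Clock 0.40, Cry1 0.11 and Nfil3 1.66 (1.17 by its other probe, 3 of its 8 nearest spots at least 2-fold higher as well), for a median of 0.26. By their brightest probes Nfil3 was low on the control array at ZT10 alone, and Nr1d2 on the tumour-bearing array at ZT10 alone. The receptor Rora (0.07) and the cold-inducible RNA-binding proteins Cirbp (0.16) and Rbm3 (0.03) were close to 0.

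By single genes, 252 of 15601 measured at ZT10 were at least 2-fold higher in the tumour-bearing cord and 181 at least 2-fold lower. The largest increases were in Bag3, a co-chaperone of heat shock proteins (3.79), Armc10 (3.76), Wdr31 (3.54), Arhgef7, an exchange factor for small GTPases (3.45), and the homeobox gene Mkx (3.44). Next came the vomeronasal receptor Vmn1r240 (3.44), Commd8 (3.08), the cytokine receptor kinase Jak1 (2.99), Gap43, a protein of growing axons (2.93), and Klhl9 (2.89). The largest decreases were in Capza1, an actin-capping protein (-5.06), the DNA-break sensor Nbn (-2.85), the growth kinase Mtor (-2.66) and Clec16a (-2.54). Next came the endosome tether Eea1 (-2.49), Btbd3 (-2.24), the cation channel Trpm1 (-2.22), Ifi44, Usp18 and the peroxisomal import protein Pex13 (-1.95). Bag3, Wdr31, Jak1 and Klhl9 were low and Nbn, Clec16a, Ifi44 and Usp18 high on the control array at ZT10 alone. Capza1, Btbd3 and Trpm1 were low on the tumour-bearing array at ZT10 alone. Genes measured on 1 array only give bounds: Stac was at least 14.5-fold higher, Ikzf5 8.10-fold and Sprr1a 6.33-fold. Olfr285 was at least 16694-fold lower, Olfr118 2074-fold and Prdm6 4.20-fold. On the control array at ZT10 Olfr285 and Olfr118 stood at 9.49 and 6.48, against -6.71 and -5.29 on the tumour-bearing array. These bounds thus rest on bright readings of that 1 control array. Of the 156 genes at least 2-fold apart that had another measured probe, the other probes lay on the same side for 51.9% and at least 1.5-fold the same way for 15. Those of Mkx (-0.09) and Commd8 (-0.68) lay on the other side. Of the 8 nearest spots, 6 around Mkx, 4 around Wdr31, 3 around Vmn1r240 and 2 each around Commd8, Gap43 and Clec16a were at least 2-fold apart the same way. The split of the genes at least 2-fold apart depends on the scaling: 58.2% were higher with the 75th percentile and 47.1% with the median.

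At ZT22 the same comparison was made late in the dark phase. Some inflammatory and reactive glial genes were higher in the tumour-bearing cord: the monocyte chemokine Ccl2 by 2.14, the alarmin Il33 by 2.03 (0.06 by its other probe), Lcn2 by 1.86, the gelatinase Mmp2 by 1.65 and Timp1 by 1.31. Il33 and Mmp2 were low on the control array at ZT22 alone. So were Ifih1, Mlc1, Cd55, Foxc1, Klf9 and Htr1a named below, and several of the largest increases at ZT22. Haemoglobin genes were again lower, with all 5 measured erythroid markers at least 1.5-fold lower and a median of -1.81 (percentile 0). Hbb-b2 gave -1.85, Hba-a1 -1.85, Hbb-b1 -1.81 and Hba-a2 -1.75. Interferon-stimulated genes stood at a median of 0.01, with 3 of 21 at least 1.5-fold higher and 2 lower. Bst2 gave -1.43, Oas1a 0.90, Usp18 -0.74 and Ifih1 0.66.

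Reactive astrocyte genes at ZT22 had a median of 0.35 (percentile 100), 16 of 19 positive and 3 at least 1.5-fold higher. Emp1 stood at 0.77 and the chemokine Cxcl10 at 0.54 after Lcn2 and Timp1, and the 7 other probes of the members gave -0.02. Homeostatic astrocyte markers had a median of 0.16 (percentile 99.9; -0.06 over 11 other probes), 5 of 14 at least 1.5-fold higher. Mlc1 gave 1.17, and Fgfr3 (1.07), Atp1b2 (1.05) and the connexin Gjb6 (0.86) each against the sign of their other probe. Complement genes had a median of 0.23 (percentile 99.3; -0.18 over 7 other probes). Cd55 stood at 1.30 against 3 other probes, C4b at 0.82 and Cfp at -0.54. Of the cytokine and chemokine list 3 of 14 were at least 1.5-fold higher and 0 lower, its median was -0.14 and its mean 0.31. Sensory ganglion markers had a median of -0.56 (percentile 1.42) over 3 measured genes, Pou4f1 (-0.67), Avil (-0.56) and Runx1 (0.01). Meningeal and connective tissue markers had a median of 0.13 (percentile 97.6), 4 of 16 at least 1.5-fold higher and 0 lower, led by Igf2 (1.29), Slc13a4 (1.09), Foxc1 (1.02) and Fmod (0.90). Genes of glutamate, GABA and glycine signalling had a median of 0.00 at percentile 97.8, which was -0.20 over 26 other probes and held in 0 of 6 other settings laid down in advance (-0.1461 to 0.0255). The complement and sensory ganglion calls held in 5 of the 6. Atp1b2 and C4b each had 2 of their 8 nearest spots at least 2-fold higher as well.

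The light-phase clock group had a median of -0.03 at ZT22: Nr1d1 gave 0.54, Nr1d2 -0.03, Dbp -0.39, Tef 0.71 and Hlf -0.40. The others gave Per1 0.10, Per2 -0.23, Per3 -0.23, Cry2 0.00, Ciart -0.03, Bhlhe41 -0.20, Bhlhe40 -0.39 and Usp2 0.48. In the dark-phase group Arntl gave -0.07, Clock 0.49, Cry1 0.23 and Nfil3 -0.36, for a median of 0.08. Rora gave 0.01, Cirbp 0.09 and Rbm3 0.46.

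At ZT22, 366 of 15566 measured genes were at least 2-fold higher in the tumour-bearing cord and 60 at least 2-fold lower. On the control array at ZT22 alone 355 spots lay at least 2-fold below the other 3 arrays and 26 above, against 53 and 51 on the tumour-bearing array at ZT22. This count was chosen after the results were seen. It covers probes of any kind, and 106 of the 355 were not well above background on that array and cannot be among the 366 genes. The largest increases were in Serpine2, a protease inhibitor (4.99, -0.25 by its other probe), Cmtm6 (4.48), Arhgef7 (3.66, -0.43 over 3 other probes) and Vmn1r240 (3.64). Next came the amyloid precursor App (3.60, -0.06 by its other probe), B3gnt2 (3.38), Kctd3 (3.07, -0.21 over 2 other probes), the ubiquitin-conjugating enzyme Ube2r2 (2.94), Dagla, which makes an endocannabinoid (2.67), and Tmem199 (2.63). The largest decreases were in Pafah1b3 (-6.38), the depalmitoylase Abhd17b (-5.19), Pde6d (-3.64), and the neuregulin receptor Erbb4 (-3.48). Next came Fbxo17 (-2.73), Hbb-bt (-2.14), the urotensin-related peptide Uts2b (-1.95), Hbb-b2, Hba-a1 and Hbb-b1. Serpine2, Cmtm6, App, B3gnt2, Kctd3 and Ube2r2 were low and Erbb4 and Fbxo17 high on the control array at ZT22 alone. Pafah1b3, Abhd17b and Pde6d were low on the tumour-bearing array at ZT22 alone. Of the 8 nearest spots, 5 each around App and Abhd17b, 4 around B3gnt2, 3 each around Vmn1r240 and Kctd3 and 2 around Tmem199 were at least 2-fold apart the same way. As bounds, Stac was at least 17.7-fold higher and Pdcl3 8.60-fold. Ucn was at least 5.83-fold lower, Trpv6 3.61-fold and Ldlrad1 2.68-fold. Of the 171 genes at least 2-fold apart with another measured probe, the other probes lay on the same side for 47.4% and at least 1.5-fold the same way for 12. With normexp background correction 25 genes were at least 2-fold lower in place of 60.

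Tumour status over both times was tested with limma (3.58.1) on the 4 arrays, with tumour and time as additive terms. 8 genes rose in tumour-bearing mice at an adjusted p under 0.05, each higher at both times: Arhgef7 (log2 3.56, standard error 0.212, adjusted p = 0.00341), Vmn1r240 (3.54, 0.00341), Dagla (2.57, 0.0213) and Gap43 (2.66, 0.0236). The others were Armc10 (3.18, 0.0317), the voltage-gated potassium channel Kcnc4 (2.23, 0.0317), Commd8 (2.61, 0.0462) and Sgk1 (1.95, 0.0489). Their probes lie on mm9 at chromosome 8, 11827008 to 11827067 (Arhgef7), chromosome 7, 20707065 to 20707124 (Vmn1r240), chromosome 19, 10319766 to 10319825 (Dagla) and chromosome 16, 42248714 to 42248773 (Gap43). The others lie at chromosome 5, 21168330 to 21168389 (Armc10), chromosome 3, 107241564 to 107241623 (Kcnc4), chromosome 5, 72550636 to 72550695 (Commd8) and chromosome 10, 21719390 to 21719449 (Sgk1). At an unadjusted p under 0.05 there were 516 genes higher and 197 lower. Together these did not exceed the share of 0.05 of the 15284 genes tested that would pass with no effect. After adjustment 0 genes passed in the lower direction. The 5 lowest in p were Hbb-b1 (-1.79, adjusted p = 0.0649), Hba-a1 (-1.60, 0.167), Hba-a2 (-1.53, 0.184), Vipr2, a receptor for vasoactive intestinal peptide (-1.40, 0.184), and Hbb-b2 (-1.50, 0.224), each lower at both times.

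Adjustment over a list alone was made within each list and not across the lists, so some lists would hold a pass with no effect. Among the gene lists in this fit, adjusted over the list alone, all 4 haemoglobin genes of the erythroid list passed as lower (0 over all genes tested). Likewise 3 of 19 glucocorticoid-responsive genes passed as higher, Sgk1, Lcn2 (1.65) and Klf9 (1.21, -0.59 by its other probe; 1 of the list, Sgk1, over all genes). The median of that list was -0.02 and its mean 0.27. Adjusted over the list alone, 2 of 19 reactive astrocyte genes passed as higher, Lcn2 and Timp1 (1.37), and 2 of 10 acute-phase genes, Lcn2 and the interleukin-1 receptor Il1r1 (1.39). So did 1 each of the cytokines, Ccl2 (1.68), and the heat shock genes, Hspb1 (1.61), with 0 of these lists over all genes. The heat shock list had a median of -0.14 and a mean of 0.16. Homeostatic astrocyte markers had a median of 0.23 with 14 of 14 positive and 0 past either adjustment. Reactive astrocyte genes had 0.18 (-0.11 over 7 other probes) and complement genes 0.18 (-0.01 over 7 other probes). The gene for dynorphin, Pdyn (1.38), passed adjusted over the neuropeptide list alone, where 5 of the 8 nearest spots were at least 2-fold higher as well. Pdyn was lowest on the control array at ZT10, at 1.90 against 3.49 to 4.35 elsewhere. Gap43 was the 1 pan-neuronal gene to pass, both over the list alone and over all genes. The pan-neuronal median was -0.03 with a mean of 0.19. Of the myelin genes Cnp (1.09, 2 of its 8 nearest spots at least 2-fold higher as well) and Mal (-0.92) passed adjusted over the list alone, in opposite directions. Motor neuron markers had a median of -0.19 (percentile 1.39), 2 of 12 at least 1.5-fold lower, led by Uts2b (-1.28) and the choline transporter Slc5a7 (-0.65), with 0 past either adjustment and the call held in 5 of 6 other settings laid down in advance.

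On simulated data the same fit gave 9.31% false calls among its calls at the nominal 5% level, and with no effect simulated 25% of the simulations still gave a call, up to 15 in 1 simulation, more than the 8 called here. The simulated arrays had noise alike on all arrays, without disturbed spots or the surplus of low spots on the control arrays. They therefore do not give the error rate of the 8 genes. The error rests on 1 residual degree of freedom, the difference of the tumour effect between the times, and on a prior of 6.29 degrees of freedom shared by all genes. The 3 other probes of Arhgef7 averaged -0.16 with 1 of 3 on the same side, and other probes gave 0.32 for Armc10, 0.07 for Kcnc4 and 0.32 for Commd8. Of the 8 nearest spots, 3 around Vmn1r240 and 2 around Gap43 were at least 2-fold higher as well. The count of 8 became 4 with quantile normalization, 2 with median scaling and 21 with normexp background correction. It became 16 when transcripts without a RefSeq gene name were tested too, and 0 without the detection filter.

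Lists drawn from pain biology were read in the same comparisons, because the study's title concerns tactile pain. Of 22 ion channels tied to pain 1 was at least 1.5-fold lower with tumour at ZT10 (median -0.06) and 1 at least 1.5-fold higher at ZT22 (median -0.12), and Trpc5 was that channel both times, at -1.10 and 0.75, each against the sign of its other probes. Receptors for noradrenaline and serotonin had medians of -0.01 and 0.04, with Htr3a at 0.61 and 1.14, its other probe on the same side, and Htr1a at -0.61 and 1.76. Neuropeptides and their receptors had medians of 0.10 and 0.00, with Grp, the gene for gastrin-releasing peptide, at 1.12 and 0.71. Homeostatic microglia markers had medians of 0.10 and 0.06 and activated microglia genes of 0.06 and -0.06, with 1 of 19 activated genes at least 1.5-fold higher at each time and 1, Spp1 (-0.67), at least 1.5-fold lower at ZT22. Acute-phase genes had medians of 0.22 and 0.21 with Il1r1 at 1.46 and 1.32. At ZT10 2 of the 8 nearest spots around each of Trpc5, Grp and Il1r1 were at least 2-fold apart the same way. In the limma fit 0 members of the ion channel, receptor and microglia lists passed over the list alone or over all genes.

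**Figure D1:**
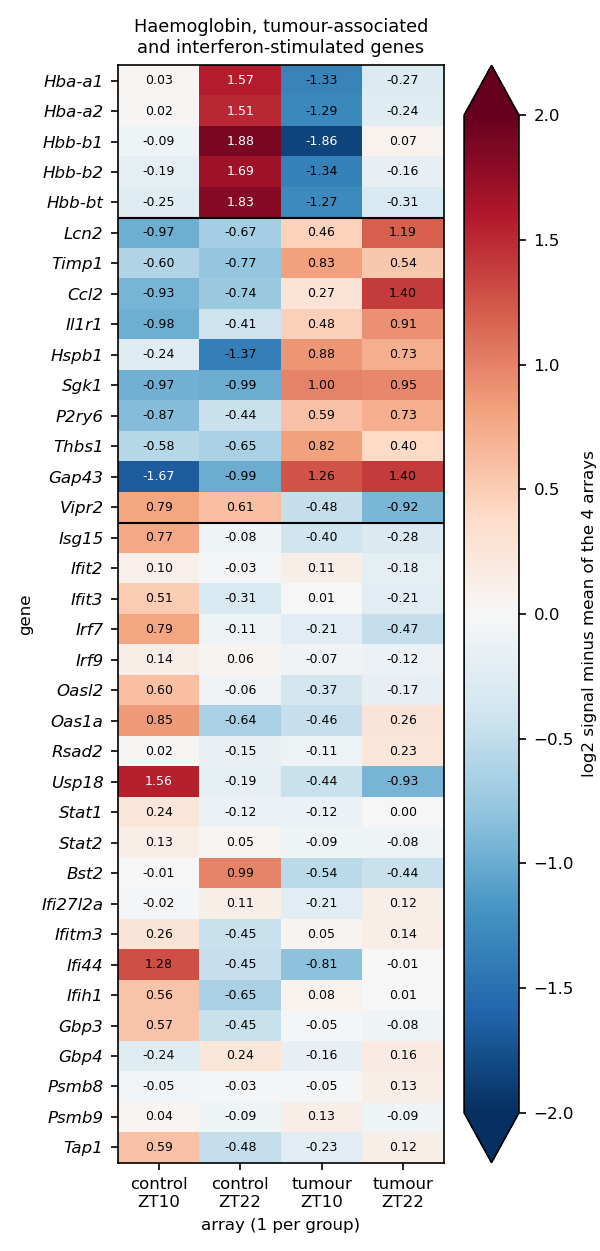
Log2 signal relative to the mean of the 4 arrays (colour) for haemoglobin genes, genes higher or lower in tumour-bearing mice at both times that were chosen after their values were seen, and the 21 interferon-stimulated genes measured on all 4 arrays; columns are the 4 arrays, 1 per group. Hbb-b1 is lowest in the tumour-bearing array at ZT10 (-1.86) and highest in the control array at ZT22 (1.88), and Usp18 is highest in the control array at ZT10 (1.56).

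In control mice, late dark was set against late light phase to show the daily difference in a healthy cord. Clock genes of the light-phase limb were lower at ZT22: 12 of 13 were negative, 4 were at least 1.5-fold lower and 0 higher, and the median of -0.46 lay below all 10000 random lists matched on expression. Nr1d1 gave -1.54, the output factor Dbp -0.92, the deubiquitinase Usp2 -0.80 and Per1 -0.68. Arntl, which REV-ERBs repress, was higher by 0.63, with its 2 other probes on the same side. Haemoglobin genes were higher at ZT22, with all 5 measured erythroid markers at least 1.5-fold higher and a median of 1.54. Interferon-stimulated genes were lower, 11 of 21 at least 1.5-fold lower and 1 higher, with a median of -0.67. That difference shares the control array at ZT10 with the tumour effect at ZT10.

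The remaining light-phase clock genes in control mice were Nr1d2 (-0.20, against the sign of its other probe), Tef (-0.29), Hlf (0.04), Per2 (-0.32), Per3 (-0.47), Cry2 (-0.46), Ciart (-0.54), Bhlhe41 (-0.11) and Bhlhe40 (-0.13). In the dark-phase group Nfil3, which represses genes that Dbp activates, gave 1.74, Clock -0.20 and Cry1 -0.07, for a median of 0.28. Nfil3 was low on the control array at ZT10 alone, a reading that also enters its tumour effect at ZT10. Rora gave -0.08, Cirbp -0.74 (0.04 over 2 other probes) and Rbm3 -0.87. The haemoglobin values were 1.97 for Hbb-b1, 1.88 for Hbb-b2 and 1.54 for Hba-a1, and the erythroid haem enzyme Alas2 gave 1.53. Among interferon-stimulated genes Usp18 and Ifi44 gave -1.74 each, Oas1a -1.49 and the RNA sensor Ifih1 -1.21. Cytokines and chemokines had a median of -0.31 (percentile 0.08), 3 of 14 at least 1.5-fold lower and 2 higher. Il33 stood at -2.03 against the sign of its other probe, Mmp2 at -1.44, Cxcl10 at -0.96 and Il18 at 0.81. Ependymal markers had a median of 0.53 (percentile 99.8), 4 of 8 at least 1.5-fold higher, led by Dynlrb2 (0.92), Tmem212 (0.71), Cdhr4 (0.63) and Ccdc153 (0.60). Homeostatic astrocyte markers had a median of 0.32 (percentile 99.7) and a mean of 0.06, with Mlc1 at -1.22, S100b at -0.89, Sox9 at 0.72 and Aldh1l1 at 0.71. Genes of glutamate, GABA and glycine signalling had a median of -0.15 (percentile 0.17; 0.10 over 25 other probes). The glycine transporter Slc6a5 stood at -1.17 and Slc12a5 at -0.50, and Gad1 (-0.68) went against the sign of its other probe. Of 6 other settings laid down in advance, the homeostatic astrocyte call held in 3, and the cytokine and the glutamate, GABA and glycine calls in 5. Dbp, Ciart and S100b each had 2 of their 8 nearest spots at least 2-fold lower as well.

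In control mice 261 of 15483 genes were at least 2-fold higher at ZT22 and 352 at least 2-fold lower. The largest increases were in Erbb4 (4.31), Bag3 (3.93), Klhl9 (3.12), Dnajb3 (3.01) and Cadps2 (2.74). Next came Wdr31 (2.73, -0.45 over 2 other probes), Jak1 (2.67), Fbxo17 (2.64), the translation initiation factor Eif5b (2.53) and the nuclear envelope protein Sun1 (2.52, 0.28 over 4 other probes). The largest decreases were in Cmtm6 (-3.71), Ypel5 (-3.55), Serpine2 (-3.27, 0.47 by its other probe), Adgrg1 (-3.26) and B3gnt2 (-3.18). Next came Nbn (-3.14), App (-3.13, 0.12 by its other probe), Dnajc13 (-2.77), Cacng5 (-2.73) and Hnrnpul2 (-2.66, 0.09 by its other probe). Bag3, Klhl9, Dnajb3, Cadps2, Wdr31, Jak1, Eif5b and Sun1 were low and Nbn high on the control array at ZT10 alone. Erbb4 and Fbxo17 were high on the control array at ZT22 alone. Cmtm6, Ypel5, Serpine2, Adgrg1, B3gnt2, App, Dnajc13, Cacng5 and Hnrnpul2 were low on that array alone. All of these largest differences thus stood apart on a single array. Each such reading also enters the tumour effect at that time. Of the 8 nearest spots, 5 around App, 4 each around Wdr31 and B3gnt2, 3 each around Sun1 and Dnajc13 and 2 each around Dnajb3, Jak1 and Eif5b were at least 2-fold apart the same way. As bounds, Cys1 was at least 6.32-fold higher at ZT22, Olfr1466 5.88-fold and the cell cycle factor E2f5 4.80-fold. Olfr285 was at least 15446-fold lower, Olfr118 1919-fold and Pdcl3 9.42-fold. For Olfr285 and Olfr118 the control array at ZT22 gave -6.56 and -5.22. Their bounds rest on the same bright readings of the control array at ZT10 as those for tumour at ZT10. Of the 249 genes at least 2-fold apart with another measured probe, the other probes lay on the same side for 53.4% and at least 1.5-fold the same way for 28. With median scaling 29.1% of the genes at least 2-fold apart were higher at ZT22 in place of 42.6%, and the median of all genes moved from 0.06 to -0.05.

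In tumour-bearing mice the same times were compared, to show the daily difference in the presence of a tumour. Light-phase clock genes were lower at ZT22 here as well: 5 of 13 were at least 1.5-fold lower and 2 higher, and the median of -0.46 lay below all 10000 random lists. Dbp gave -1.78, with -1.65 by its other probe, Nr1d1 -0.93, and the period genes Per2 -0.88 and Per1 -0.85. Arntl gave 0.49 with both other probes on the same side. Haemoglobin genes were higher at ZT22, with all 4 measured erythroid markers at least 1.5-fold higher and a median of 1.12. Hbb-b1 gave 1.92, Hbb-b2 1.19, Hba-a1 1.06 and Hba-a2 1.05. Interferon-stimulated genes had a median of 0.09, 2 of 21 at least 1.5-fold higher and 0 lower. Ifi44 stood at 0.80, Oas1a at 0.72, Usp18 at -0.49 and Rsad2 at 0.34.

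The other light-phase clock genes in tumour-bearing mice were Nr1d2 (0.95, 1 of 2 other probes on the same side), Tef (0.59, -0.13 with the mean of its probes), Hlf (-0.10), Per3 (-0.58), Cry2 (-0.14), Ciart (-0.24), Bhlhe41 (-0.46), Bhlhe40 (-0.60) and Usp2 (-0.32). The brightest probe of Nr1d2 was low on the tumour-bearing array at ZT10 alone, a reading that also enters its tumour effect at ZT10. In the dark-phase group Clock gave -0.12, Cry1 0.06 and Nfil3 -0.27, for a median of -0.03. Rora gave -0.15, Cirbp -0.82 and Rbm3 -0.44. Immediate early genes, which neurons switch on within minutes of activity, had a median of -0.23 (percentile 0.59), 2 of 19 at least 1.5-fold lower. Npas4 stood at -0.75, Nr4a1 at -0.68, Fos at 0.48 and Egr1 at -0.46. Cell cycle genes had a median of -0.29 (percentile 0.77; 0.09 over 4 other probes), with Mcm5 at -0.72, Mcm2 at -0.57, Mki67 at -0.51 and Plk1 at -0.40. Cholesterol synthesis genes had a median of -0.19 (percentile 2.36) with 0 of 16 at least 1.5-fold apart, Nsdhl at 0.48, Insig1 at -0.39, Mvd at -0.36 and Cyp51 at -0.35. This call held in 0 of 6 other settings laid down in advance. Meningeal and connective tissue markers had a median of 0.23 (percentile 99.7), endothelial markers 0.16 (percentile 98.1) and complement genes 0.15 (percentile 97.8). Neuropeptides and their receptors had a median of 0.10 (percentile 99.7), homeostatic astrocyte markers 0.08 (percentile 98.6) and myelin genes 0.04 (percentile 97.8, mean -0.02). Of the same 6 settings, the myelin call held in 2, the homeostatic astrocyte and complement calls in 3, the immediate early call in 4, and the neuropeptide and cell cycle calls in 5. Neutrophil and marrow markers had a median of 0.41 (percentile 98.3), with Chil3 at 1.84 (2 of its 8 nearest spots at least 2-fold higher as well), S100a9 at 0.76, Camp at 0.55 and Mpo at -0.36.

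In tumour-bearing mice 207 of 15680 genes were at least 2-fold higher at ZT22 and 45 at least 2-fold lower. The largest increases were in Capza1 (5.33), Hbs1l (2.48, -0.04 by its other probe), Mtor (2.37, 0.84 by its other probe) and Trim67 (2.26). Next came the integrin subunit Itgav (2.26), the stress kinase Mapkapk2 (2.18), Edem3 (2.03, 0.66 over 2 other probes), Stk35 (2.00, -0.20 by its other probe), Btbd3 (1.98) and the ubiquitin ligase Cblb (1.97). The largest decreases were in Pafah1b3 (-6.22), Abhd17b (-4.98), Pde6d (-3.49) and Xlr4b (-2.43). Next came the relaxin-family peptide receptor Rxfp3 (-1.96), Tspyl5 (-1.95), Dbp, the meiotic genes Tex11 (-1.56) and Syce1 (-1.53), and Slc6a20a (-1.45). Capza1, Trim67, Itgav, Mapkapk2, Edem3 and Btbd3 were low and Xlr4b, Tex11 and Syce1 high on the tumour-bearing array at ZT10 alone. Pafah1b3, Abhd17b, Pde6d and Slc6a20a were low and Hbs1l and Cblb high on that at ZT22 alone. Each such reading also enters the tumour effect at that time. Of the 8 nearest spots, 5 each around Abhd17b and Slc6a20a, 3 around Stk35 and 2 each around Hbs1l, Mtor, Itgav, Mapkapk2, Edem3, Cblb and Pde6d were at least 2-fold apart the same way. As bounds, the transcription factor En1 was at least 7.18-fold higher at ZT22 and Cys1 6.64-fold. Baiap2l1 was at least 4.32-fold lower, Ucn 2.82-fold and Axin2 2.67-fold. Of the 87 genes at least 2-fold apart with another measured probe, the other probes lay on the same side for 47.1% and at least 1.5-fold the same way for 11. With normexp background correction 92 genes were at least 2-fold higher and 11 lower.

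**Figure D2:**
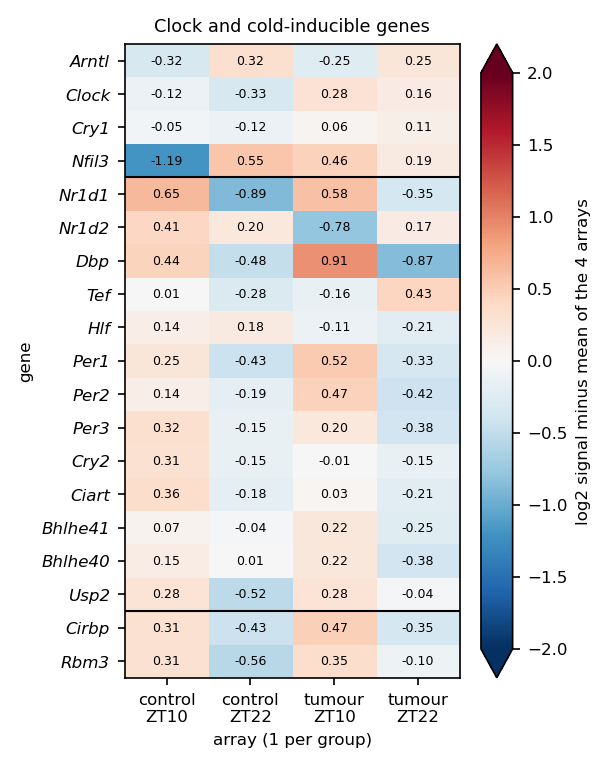
Log2 signal relative to the mean of the 4 arrays (colour) for the measured clock genes and cold-inducible genes; columns are the 4 arrays, 1 per group, and lines part the gene groups. Nr1d1 stands at 0.65 and 0.58 in the arrays at ZT10 and at -0.89 and -0.35 in those at ZT22.

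Time of day over both kinds of mice was tested in the same limma fit. 0 genes passed an adjusted p under 0.05 in either direction, against 482 higher and 281 lower at ZT22 at an unadjusted p under 0.05. Together these counts did not exceed the share of 0.05 of the 15284 genes tested that would pass with no effect. The smallest adjusted p was 0.186. In the light-phase clock group Nr1d1 (log2 -1.23, adjusted p = 0.648 over all genes), Dbp (-1.35, 0.648) and Per1 (-0.77, 0.877) fell when adjusted over the list alone, 3 of 13 members, each lower at ZT22 in both kinds of mice. The group's median was -0.39 (percentile 0). The probe of Nr1d1 spans 98630526 to 98631028 on chromosome 11 of mm9, and that of Dbp lies at 52965461 to 52965520 on chromosome 7. The dark-phase group had a median of 0.28 (percentile 97.6) with Arntl at 0.56, Nfil3 at 0.73, Clock at -0.16 and Cry1 at 0.00. 0 members of it passed over the list alone, and its call held in 3 of 6 other settings laid down in advance. Adjusted over the list alone the 4 haemoglobin genes rose at ZT22, from 1.27 for Hba-a2 to 1.95 for Hbb-b1. So did 2 of 5 neutrophil and marrow markers, S100a9 (1.52) and the antimicrobial peptide Camp (0.76), with 0 of both lists over all genes.

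Of the genes of fasting and lipid metabolism the lipase inhibitor Angptl4 (0.83) also rose when adjusted over the list alone. So did the tight-junction gene Cldn5 (1.11), 1 of 13 endothelial markers, and Herpud1 (1.75, -0.42 by its other probe), 1 of 17 genes of the stress and unfolded protein responses. The adipokine Retn (-0.76), 1 of 3 adipocyte markers, fell. 0 members of these lists passed over all genes. Oxidative phosphorylation genes had a median of 0.18 (percentile 99.97), 17 of 20 positive and 0 at least 1.5-fold apart, a call held in 5 of the 6 settings. Cox6c stood at 0.51, Ndufa4 at 0.49, Sdha at 0.49 against 2 other probes and Atp5g3 at 0.48 against its other probe. Immediate early genes had a median of -0.22 (percentile 0.07) and interferon-stimulated genes -0.23 (percentile 0.02), with 0 members of either past the list alone. The interferon median rests on control mice, at -0.67, and that list had no call across time in tumour-bearing mice. It is thus not a difference shared by both kinds of mice. The lowest p among genes higher at ZT22 belonged to Tcf19 (1.96, adjusted p = 0.186), Hbb-b1 (1.95, 0.186), Zfp867 (1.87, 0.548), Fam126b (1.44, 0.548, -0.90 by its other probe) and Efhd1 (1.71, 0.548, -0.17 by its other probe, 2 of its 8 nearest spots at least 2-fold higher as well). Among genes lower at ZT22 it belonged to Rxfp3 (-1.87, 0.186), Cdyl (-1.31, 0.548), Dmrtc1a (-1.46, 0.648), Tcap (-1.23, 0.648) and Nr1d1. In simulations this fit recovered 16.3% of genes that differed 2-fold and 97.9% of those that differed 4-fold. With the mean of each gene's probes 2 genes passed as higher and 1 as lower.

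The difference of the tumour effects, ZT22 less ZT10, shows where tumour status went with another size or direction at the other time. With 1 array per group it was not tested. Interferon-stimulated genes gave a median of 0.60 (percentile 99.99), 11 of 21 at least 1.5-fold higher at ZT22 than at ZT10 and 1 lower. Ifi44 stood at 2.54, Oas1a at 2.21, Tap1 at 1.41 against the sign of its other probe and Usp18 at 1.25. Cytokines and chemokines gave a median of 0.31 (percentile 99.5), led by Mmp2 (1.85) and Il33 (1.56, -0.04 by its other probe). Ependymal markers gave -0.66 (percentile 0.09), with Cdhr4 at -1.54 and Dynlrb2 at -0.87, meningeal and connective tissue markers 0.25 (percentile 99.1), and genes of glutamate, GABA and glycine signalling 0.17 (percentile 99.9; -0.36 over 24 other probes). The cytokine and the glutamate, GABA and glycine calls held in 5 of 6 other settings laid down in advance. By single genes 694 of 15284 were at least 2-fold higher and 416 at least 2-fold lower. The largest positive differences were Capza1 (5.22), Mtor (4.50), Cmtm6 (4.09), Serpine2 (3.62, -0.80 by its other probe) and Pla2g4e (3.38). The largest negative ones were Pafah1b3 (-6.45), Abhd17b (-4.65), Erbb4 (-3.69), Pde6d (-3.58) and Bag3 (-3.21). Capza1, Cmtm6, Serpine2, Pafah1b3, Abhd17b, Erbb4, Pde6d and Bag3 each stood apart on a single array, by the same readings as in the pairs above. Of the 8 nearest spots, 5 each around Pla2g4e and Abhd17b and 2 each around Mtor, Cmtm6, Pafah1b3 and Pde6d were at least 2-fold apart the same way.

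**Figure D3:**
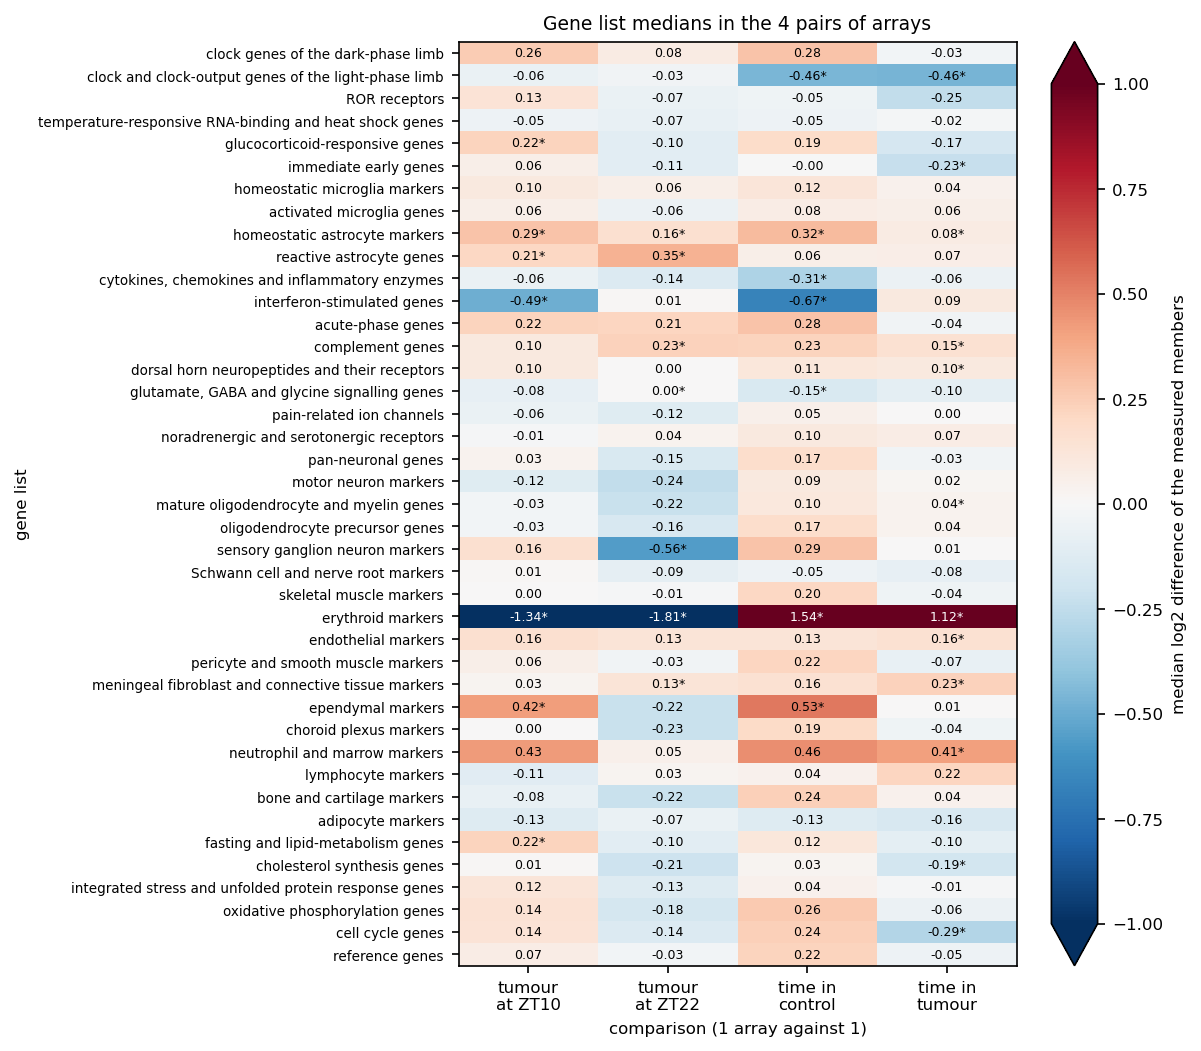
Median log2 difference (colour and printed value) of the measured members of each of the 41 gene lists, one list per line, in the 4 comparisons of 1 array against 1; an asterisk marks a median outside percentiles 2.5 to 97.5 of random lists of the same size. Erythroid markers are lower with tumour (-1.34 and -1.81) and higher at ZT22 (1.54 and 1.12), and light-phase clock genes are lower at ZT22 (-0.46 in both).

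The effects at the 2 times, and in the 2 kinds of mice, were set side by side across genes, which are not independent replicates. The tumour effects at ZT10 and ZT22 had a Pearson r of 0.013 and a Spearman rho of -0.0286 over 15284 genes, and the time effects in control and tumour-bearing mice an r of -0.0179 and a rho of -0.0025. At least 2-fold higher with tumour at both times were 43 genes, where independent effects would give 5.79, and 7 were lower at both (0.61), while 33 went opposite ways (4.9986). Genes at least 2-fold apart at both times thus exceeded chance in opposite directions too. Among the 43, chosen here after their values were seen, were Lcn2, Timp1, Ccl2, Il1r1, Hspb1, the nucleotide receptor P2ry6 (1.46 at ZT10 and 1.17 at ZT22) and the matrix protein Thbs1 (1.40 and 1.05). The 7 were 5 haemoglobin genes, Pex13 and Vipr2. At least 2-fold higher at ZT22 in both kinds of mice were 18 genes (3.33 by chance), 4 haemoglobin genes, Herpud1, Id2 and Tcf19 among them, and 2 were lower in both (0.99), Cdyl and Rxfp3, with 33 going opposite ways (5.30). Averaged over arrays, 674 genes differed at least 1.5-fold by tumour, 730 by time and 727 by the crossed split of the 4 arrays, which belongs to neither factor.

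**Figure D4:**
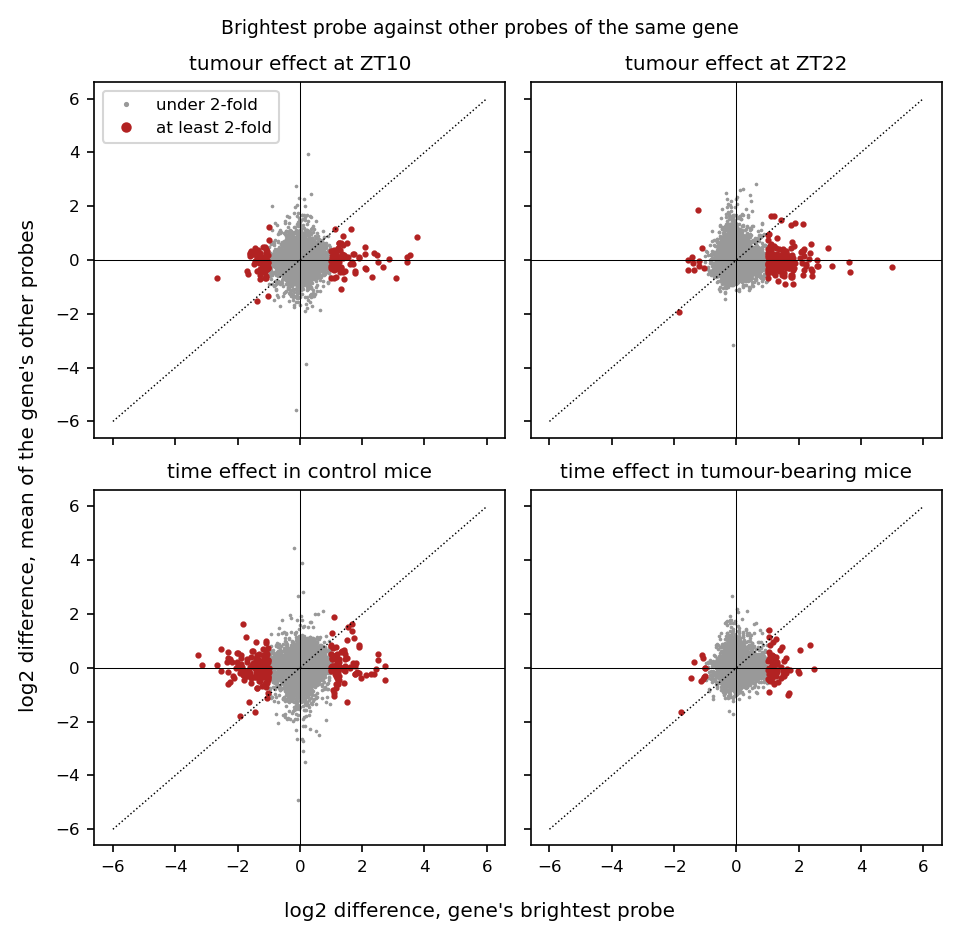
Log2 difference of each gene's brightest probe (horizontal axis) against the mean of its other measured probes (vertical axis) in the 4 comparisons, 6868 to 7019 genes each; red points are genes at least 2-fold apart by the brightest probe, and the dotted line marks equal values. The red points spread about 0 on the vertical axis, with medians in the direction of the gene's difference from -0.01 to 0.03.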

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

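All of the explanations weighed here were tested only after the result concerned was seen, so each is a hypothesis found and tested on the same 4 arrays.

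Genes at least 2-fold apart between a pair of arrays were mostly not followed by their other probes where these could be checked. Only 156, 171, 249 and 87 of these genes in the 4 comparisons had another measured probe, fewer than had none. In these the other probes had a median in the gene's own direction of at most 0.0286 on the log2 scale, where the brightest probes had 1.17 to 1.35, which is consistent with single disturbed spots. An effect of tumour or time on the whole gene as the main cause in the genes with another probe is argued against by the share of other probes with the same sign, at most 53.4%. Different transcripts of 1 gene as the whole cause is argued against by the slide: genes at least 2-fold apart had at least 3.63 times as many neighbouring spots 2-fold apart the same way as other genes. Only 21.0%, 17.6%, 19.2% and 11.9% of these genes in the 4 comparisons had at least 2 such neighbours. Without them 187 genes higher and 155 lower, 296 and 55, 208 and 287, and 182 and 40 were left. A true difference in single genes stays open, as it does for genes with 1 measured probe and for the 8 genes that passed in limma over both times.

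Haemoglobin transcripts were lower in tumour-bearing mice at both times and higher at ZT22 in both kinds of mice. All 6 haemoglobin probes that were well above background on all 4 arrays lay between -1.79 and -1.50 for tumour and between 1.27 and 1.95 for time. The other probe gave -1.73 for tumour, which together with these values argues against single disturbed spots. Fewer vessels in the tumour-bearing samples is argued against by the endothelial markers, whose median was higher with tumour by 0.14. Less residual blood in the tumour-bearing samples cannot be told apart from fewer young red cells, since the neutrophil and lymphocyte medians with tumour were 0.33 and -0.11 over only 5 and 4 measured markers. At ZT22 they were 0.47 and 0.12, the same way as haemoglobin, so more residual blood at ZT22 was not tested apart and stays open. An effect of the tumour or of the hour on haemoglobin transcripts is the biological explanation the design names. In the limma fit above these genes passed for both over the list alone and for neither over all genes. That fit cannot part such an effect from residual blood, so the explanation stays open with 1 array per group.

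Interferon-stimulated genes stood highest on the control array at ZT10, so they were lower both with tumour at ZT10 and at ZT22 in control mice. The same array enters the tumour effect at ZT22 less that at ZT10, which was 0.60 with medians of opposite sign at those times. Single disturbed spots are argued against by the 6 other probes of these genes, 5 of them lower with tumour at ZT10 and their median -0.61. Scaling or background correction is argued against by the alternative that moved the list most towards 0, which still gave -0.31. On the control array at ZT10 the list lay 0.35 above the mean of the other 3 arrays, against -0.16 to -0.11 for each of the others, so 1 sample that differs from its group may account for it. That cannot be told apart from an effect of tumour and time together, the biological explanation the design names, without a second control array at ZT10.

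Other differences between groups were not tested and not weighed. The tumour effect at ZT22 less that at ZT10 was 0.17 for genes of glutamate, GABA and glycine signalling and -0.66 for ependymal markers, both with medians of opposite sign at those times. Mtor was lower with tumour at ZT10 (-2.66) and higher at ZT22 (1.84), and lower at ZT22 in control mice (-2.13) but higher in tumour-bearing mice (2.37). Eea1 was lower at ZT22 in control mice (-1.28) and higher in tumour-bearing mice (1.88). Stk35 was lower with tumour at ZT10 (-1.59) and higher at ZT22 (1.70), and lower at ZT22 in control mice (-1.29) but higher in tumour-bearing mice (2.00). Tspyl5 was higher with tumour at ZT10 (1.60) and lower at ZT22 (-1.54), and higher at ZT22 in control mice (1.19) but lower in tumour-bearing mice (-1.95). Pla2g4e was lower with tumour at ZT10 (-1.70) and higher at ZT22 (1.68), and lower at ZT22 in control mice (-2.32) but higher in tumour-bearing mice (1.06). In data outside the comparisons, 15 of 3840 transcripts without a RefSeq gene name were at least 2-fold higher in tumour-bearing mice at both times, where independent effects would give 3.71, and 2 were lower at both. Those going opposite ways were not counted, and named genes exceeded chance in opposite directions too. The surplus alone thus does not show a shared tumour effect.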

How the results depend on the processing

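Of the alternatives below, those with all named transcripts, without spots in disturbed neighbourhoods, with agreeing probes and with the other probes of list members were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array, and leaving out 1 array in turn does not apply, since it leaves the additive fit no residual degree of freedom.

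Among list medians with a percentile outside 2.5 to 97.5, those of the erythroid markers kept their direction and their side of those bounds under all 6 other settings that were laid down in advance (tumour -1.41 to -1.06 at ZT10 and -1.82 to -1.74 at ZT22, time 1.43 to 1.54 in control and 0.93 to 1.14 in tumour-bearing mice). So did light-phase clock genes across time (-0.57 to -0.28 in control and -0.51 to -0.39 in tumour-bearing mice) and interferon-stimulated genes (-0.57 to -0.31 with tumour at ZT10, -0.78 to -0.31 across time in control mice). Of these 6 settings, median scaling can move a percentile only through the random draws, and the authors' table nearly repeats quantile normalization. Of all values recomputed for lists 1752 were unchanged, 53 gained a call, 42 lost one, 20 moved and 17 reversed. Unchanged means that a call was kept on its side, that a list without a call stayed without one, or that the other probes' median lay within 0.296 of the main one. Direction was checked only for lists with a call in the main setting. Of those for named genes 2742 lay within 0.296 of the main value, 344 moved and 4 reversed. That limit is the largest SD of repeated-spot differences among the pairs, and only genes at least 1.5-fold apart could count as reversed. Of the main counts 108 stayed within 1.5 times and 60 did not. Of the correlations 13 stayed within the bootstrap interval of the main value and 2 did not.

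For the results below that moved or reversed, the cause was not tested unless it follows from the alternative itself. Higher and lower counts change by construction with the threshold. At 1.5-fold they were 970 and 802 for tumour at ZT10, 1101 and 486 for tumour at ZT22, 1183 and 1032 for time in control mice, 820 and 383 for time in tumour-bearing mice, and 1626 and 1836 for the difference of tumour effects. At 3-fold they were 58 and 32, 108 and 11, 57 and 89, and 38 and 8 for the 4 pairs. Without the detection filter, which adds genes at background, the pairs gave 1064 and 767, 1039 and 800, 1268 and 855, and 1001 and 618, and the difference 1677 and 1811. The fit then gave 0 genes higher with tumour (limma, 832 at an unadjusted p under 0.05), the correlation of the time effects was 0.0134, and the tumour, time and crossed contrasts held 2542, 2774 and 2635 genes. Where other probes had to agree, which needs a second probe, 8 and 7, 11 and 1, 17 and 11, and 10 and 1 were left.

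Normexp left 104 genes lower with tumour at ZT10 and 25 at ZT22, 92 higher and 11 lower across time in tumour-bearing mice, 274 lower in the difference, and 21 higher and 3 lower with tumour over both times. With it Adra2b at ZT22 reversed from 0.59 to -0.055, neuropeptides across time in tumour-bearing mice to -0.0049, and glutamate, GABA and glycine genes at ZT22 to -0.0332. With all named transcripts 93 were lower with tumour at ZT22, 69 lower across time in tumour-bearing mice, and 16 higher and 1 lower with tumour over both times. The 8 genes higher with tumour over both times became 4 with quantile normalization, 4 with the authors' table, 4 with probes well above background on at least 2 arrays, 2 with median scaling and 5 with a robust fit. An intensity trend called 2 lower. In the upper part of the expression range the correlation of the tumour effects was 0.0651.

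With median scaling glutamate, GABA and glycine genes at ZT22 reversed to -0.0058 and myelin genes across time in tumour-bearing mice to -0.005. With the mean of probes 3 genes passed as lower with tumour, 2 as higher and 1 as lower at ZT22. Tef across time in tumour-bearing mice reversed to -0.13, Klf9 with tumour at ZT10 to -0.62, Sdha across time in control mice to -0.25, and glutamate, GABA and glycine genes to -0.15 at ZT22 and -0.0509 in the difference. Myelin genes then gave -0.0022. By the other probes alone these list medians reversed: homeostatic astrocytes at ZT22 to -0.0602, reactive astrocytes at ZT22 to -0.0191 and over both times to -0.11, and complement at ZT22 to -0.18 and over both times to -0.005. So did glutamate, GABA and glycine genes at ZT22 to -0.20, across time in control mice to 0.10 and in the difference to -0.36. Oligodendrocyte precursors over both kinds of mice gave -0.0852, and cell cycle genes across time in tumour-bearing mice 0.0917.

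Signal over background limits what can be seen: 7995 of 24722 genes lay above background on no array. The lowest signal called well above background was 12.4 to 14.2. The slope of the spike-in series was 0.832 to 0.856, outside the scanner software's range on all 4 arrays.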

Other observations

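The lists below were planned, and the comparison of single-array spots was chosen only after the results were seen.

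Endothelial markers leaned higher with tumour and at ZT22. Over both times they had a median of 0.14 with tumour (percentile 99.1), 11 of 13 positive, led by the junction cadherin Cdh5 (0.77), Vwf (0.47), the receptor Flt1 (0.44) and Esam (0.38), and of 0.23 at ZT22 (percentile 99.8). Of 6 other settings laid down in advance the call for tumour held in 4 and that for ZT22 in 5. Homeostatic microglia markers had a median of 0.09 with tumour (percentile 98.4), led by Gpr34 (0.41) and Sall1 (0.40), and the dark-phase clock group 0.31 (percentile 98.0). Ependymal markers had a median of 0.23 at ZT22 (percentile 98.0). That median rests on control mice, at 0.53, and the list had no call across time in tumour-bearing mice. Neutrophil and marrow markers had 0.47 (percentile 99.5). Oligodendrocyte precursor genes had 0.18 (percentile 98.9, and -0.09 over their other probes), where the lineage factor Olig2 gave 0.95. Homeostatic astrocyte markers had 0.18 at ZT22 (percentile 99.9), cytokines and chemokines -0.16 (percentile 0.69) and genes of glutamate, GABA and glycine signalling -0.09 (percentile 2.08, a call held in 3 of 6 settings). 0 members of these lists passed in limma over all genes tested for either effect.

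The lists that follow lay within percentiles 2.5 to 97.5 in the additive fit. With tumour, Schwann cell and nerve root markers had a median of -0.07, skeletal muscle -0.13, pericytes and smooth muscle 0.04, meningeal and connective tissue 0.08, choroid plexus 0.03, lymphocytes -0.11, bone and cartilage -0.12, adipocytes -0.07, activated microglia 0.04, stress and unfolded protein response -0.02, cholesterol synthesis -0.07, cell cycle -0.08 and reference genes -0.02. At ZT22 Schwann cell markers had 0.07, skeletal muscle 0.10, pericytes 0.01, choroid plexus 0.07, lymphocytes 0.12, bone and cartilage 0.13, pain-related ion channels -0.04, noradrenergic and serotonergic receptors 0.04, glucocorticoid-responsive genes -0.05, heat shock genes 0.01 and reference genes 0.04. Across comparisons 5 to 13 of 40 lists lay outside percentiles 2.5 to 97.5, where independent lists would give 2.

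Spots that stood at least 2-fold away from the other 3 arrays on 1 array were mostly low ones. There were 335 low and 33 high spots on the control array at ZT10, 355 and 26 on the control array at ZT22, 137 and 20 on the tumour-bearing array at ZT10, and 53 and 51 on the tumour-bearing array at ZT22. Of the low spots 129, 106, 58 and 30 in this order were not well above background there. Counted spots were well above background and within 1.5-fold of each other on the other 3 arrays. Spots bright on 1 array and at background on the rest are thus left out. The control arrays correlated least with each other across genes, at 0.985, and the tumour-bearing arrays most, at 0.991. A spot low on a control array alone, if still well above background, counts as higher with tumour. Part of the genes at least 2-fold higher with tumour may thus come from such spots. Low spots had low neighbours more often: on the control array at ZT22 46.5% had one, against 12.8% of the rest.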
